A study of Homo sapiens with 8 samples.

How the data were processed

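Methylated DNA was enriched from fragmented genomic DNA with a kit that captures it by a methyl-CpG-binding protein domain (MethylCap), and was sequenced beside an input library of the same culture. Per the submitters' processing notes, cutadapt, Bowtie2 and HOMER were used with genome build hg19; their versions are not given in the sources used here. Per the file headers, the authors called peaks with HOMER findPeaks in its histone style, separately in each capture library against its own input, and did not pool donors. Candidate peaks of 500 bp were stitched into regions of variable length. A Poisson p of 0.001, at least 4-fold more tags than in input and a Poisson p-value over input of 0.0001 were required, and 1 tag per base at most was considered. Per the file headers, the resulting threshold was 15 tags in 3 libraries and 20 in the siPGR library of donor 2, which is 6.31, 6.47 and 6.43 tags per 10000000 tags of the library in the former and 5.58 in the latter.

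The deposited lists give, for each peak, the whole count of tags, a normalized tag signal that the authors scaled to 10000000 tags of the library (normalized tags), and the input tag signal scaled to the capture library. They also give the authors' fold ratio over input, the p-value over input, a findPeaks score, a clonality ratio and a region size. The tag counts summed to the total that each file header gives for tags in peaks. Because each list holds tags only for the peaks called in that library and within its own boundaries, no count model was fitted across libraries. Heights and folds are the authors' own values for each peak and served only to describe, rank or filter peaks within a list. Depth was 23189469 to 35812660 tags per capture library. Input depth was recovered from the step between scaled input values (100% of low values whole within 0.1 of a step), and was 1.26 and 1.29 times as high for siPGR as for siCtrl in donors 1 and 2. Intervals on shares of tags or regions are Wilson intervals at 95% and cover counting error only, since amplified reads are not independent molecules.

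Samples were grouped by their titles, which the genotype labels match. The labels give the donor of each library, so same-numbered libraries are paired by donor. As a check, the correlation of peak presence across merged regions was 0.158 and 0.0985 between libraries of the same donor, 0.148 and 0.13 between libraries of the same condition, and 0.103 and 0.149 between libraries that share neither. These values did not separate pairs by donor or by condition, so the pairing rests on the labels alone. The n of 2 counts donors. The sex chromosomes and mitochondrial DNA were left out throughout.

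Autosomal peaks of the 4 lists were merged into regions where they shared at least 1 bp (bedtools 2.31.1), and each region was scored for a peak in each library. Gained regions had a peak in both siPGR and neither siCtrl library, and lost regions the reverse. The crossed patterns (siPGR of donor 1 with siCtrl of donor 2, and siCtrl of donor 1 with siPGR of donor 2) served as background. Agreement of donors was measured by the odds ratio of gained and lost against crossed regions, with 95% intervals from 1000 bootstrap draws of 10 Mb blocks. Peak number was compared by the ratio of group means and an exact permutation test. Windows of 1 Mb were put in 5 groups of about equal region number by their count of regions. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

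The main comparisons and most alternatives were fixed before the data were examined. These were a reciprocal overlap of at least 50%, the upper 50% of each list, lists of equal length, fixed bins of 1 kb with at least 200 bp covered, absence of any peak of the other condition within 1 kb, peaks at least 8-fold over input for the peak number, covered bases, stratification by width, leaving out each donor, and fits with and without the replicate block. Added after the data were seen were a common floor of 10 normalized tags, peaks at 1.5 and 2 times the caller's tag threshold (by the findPeaks score), regions at least 8-fold over input, the gain to loss ratio itself, and the comparisons by chromosome, window, peak density and peak length. By the rule fixed beforehand, named regions are the 10 gained and 10 lost ones with the highest lower percentile of normalized tag count in the 2 lists that hold them. The 5 highest at least 8-fold over input, the longest regions and the windows with the largest excess were chosen after their values were seen. The planned results by promoter, exon, intron, CpG island, fixed gene list and GC content need an annotation or sequence of hg19 and were not run, so no gene list is reported.

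The steps were tested on simulated lists at the 366587 real regions. Each library was given its real share of these regions, drawn with the same probability at every region. Where libraries were independent, the log2 odds ratio was 0.02 (-0.02 to 0.06). With 2000 gains and 2000 losses planted it was 0.27, the value of the simulated truth, and 99.5% of the true number of gained regions was counted in each simulation.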

Results

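Methylated DNA was captured and sequenced from primary uterine leiomyoma cells, which are cultured cells of a benign smooth muscle tumour of the uterus. The cells came from 2 donors. Each culture was transfected for 72 h with a control siRNA (siCtrl) or with an siRNA against PGR, the progesterone receptor gene (siPGR), and was then stimulated for 24 h with R5020, a synthetic progestin, at 1e-07 M. The series holds 8 samples, of which 4 are capture libraries with a peak list, 2 per condition and 1 of each condition per donor. The other 4 are input libraries, which enter only through the input values that the peak lists carry. Sequencing depth was 23782669 tags for siCtrl and 23189469 for siPGR in donor 1, and 23316459 and 35812660 in donor 2. Peak heights are the authors' normalized tags, that is tags in the peak per 10000000 tags of the library. Peaks are reported on the 22 autosomes in hg19 coordinates. Gene annotation of this build was not used here, so regions are given by position.

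The grouping follows the sample titles and genotype labels, with 1 limit that bears on every comparison. The header of 1 of the 2 peak lists labelled siCtrl names a tag directory of a PGR siRNA, so the contrast in 1 donor may be between PGR siRNAs. The source names of all 8 samples also give the other siRNA than their titles. If they held, every gain, loss, gain to loss ratio and ratio of siPGR to siCtrl below would turn over. The odds ratio for change in the same direction in both donors would not move. The headers of 3 of the 4 peak lists name the condition of the title. The siRNA does not alter the sequence of the DNA, so peaks at any locus cannot check the knockdown. "siCtrl" below means the libraries labelled so, and the values of each donor are given beside the pooled peak numbers, covered sequence, tag shares, long peaks and gain to loss ratio.

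The first comparison asked how much of the genome was captured as methylated in each condition. The siPGR libraries had more peaks, more covered sequence and more peaks of at least 10 kb than the siCtrl library of the same donor, in both donors. Autosomal peaks numbered 213521 ± 18311 in siCtrl and 244772 ± 11087 in siPGR (SD, n = 2), a ratio of 1.15, with 1.18 in donor 1 and 1.12 in donor 2. The peaks covered 206.1 ± 17.5 Mb in siCtrl and 250.7 ± 15.0 Mb in siPGR (SD, n = 2), from 193.7 to 240.1 Mb in donor 1 and from 218.5 to 261.2 Mb in donor 2. The share of all tags that lay in peaks was 31.6% in siCtrl and 43.6% in siPGR in donor 1, and 37.3% and 45.7% in donor 2, with 95% Wilson intervals of 31.59 to 31.63%, 43.61 to 43.65%, 37.28 to 37.31% and 45.64 to 45.67% in the same order. Tag density within the covered sequence was 16.4 ± 0.51 normalized tags per kb in siCtrl and 17.5 ± 0.49 in siPGR (SD, n = 2). Each of these 4 measures was higher in both siPGR libraries than in both siCtrl libraries. The exact two-sided permutation test of 2 libraries against 2 gave p = 0.333 for each, the smallest value this design allows. Among peaks at least 8-fold over input, the ratio was 1.27 in donor 1 and 0.839 in donor 2, so the higher peak number did not hold in both donors at this fold. Among peaks of at least 2 times the caller's tag threshold, chosen after the data were seen, the ratio was 2.77 in donor 1 and 3.11 in donor 2.

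**Figure D1:**
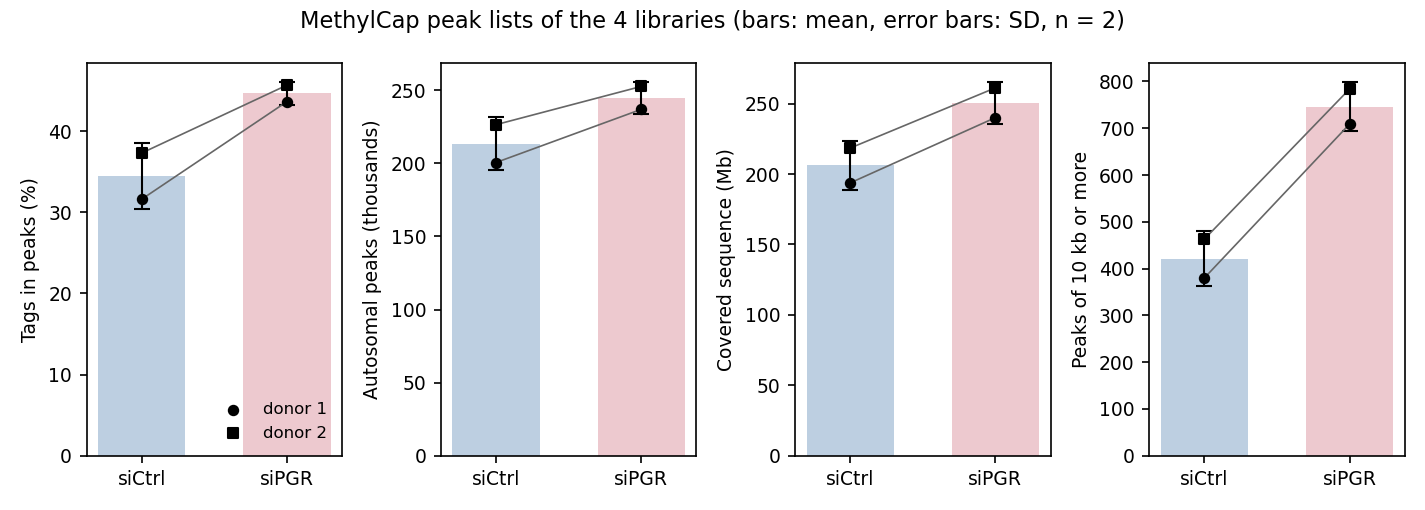
Percent of tags in peaks, autosomal peaks (in units of 1000), covered autosomal sequence (Mb) and peaks of at least 10 kb for siCtrl and siPGR; bars are means, error bars SD (n = 2), points single libraries, and lines join libraries of 1 donor. All 4 measures lie higher in siPGR in each donor, with 380 and 463 long peaks in siCtrl and 709 and 784 in siPGR.

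Long peaks were also more numerous in siPGR. Peaks of at least 10 kb numbered 380 in siCtrl and 709 in siPGR in donor 1, and 463 and 784 in donor 2, a ratio of means of 1.77. The stretches of the genome under these peaks were not confined to 1 condition. All 709 and all 784 long siPGR peaks overlapped siCtrl peaks of the same donor in the same merged region, where the siCtrl list held a median of 3 shorter pieces in each donor and a longest piece of 8954 bp and 9493 bp at the median. These peaks were selected for their length in siPGR. In the reverse direction, the regions of the 380 and 463 long siCtrl peaks held a median of 2 siPGR pieces, with a longest piece of 13909.5 bp and 13377 bp at the median. Of the 1564 merged regions of at least 10 kb, 1563 had a peak in all 4 libraries. The longest region ran over 57.4 kb of chromosome 7 (2144394 to 2201809), of which 49.0 ± 4.1 kb was covered in siCtrl and 52.9 ± 0.88 kb in siPGR (SD, n = 2). The next longest lay on chromosome 16 (88924704 to 88981401), with 52.4 ± 0.55 kb covered in siCtrl and 54.5 ± 0.24 kb in siPGR (SD, n = 2). A further region on chromosome 7 (2602780 to 2658433) had 43.001 kb covered in siCtrl and 46.5 kb in siPGR in donor 1, and 48.3 kb and 52.4 kb in donor 2.

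The second comparison asked which regions carried a peak in one condition and not in the other. Peaks of the 4 lists merged into 366587 regions, of which 83624 (22.8%) were found in all 4 libraries and 119907 (32.7%) in only 1. In both donors, 23311 regions were gained, with a peak in each siPGR and in neither siCtrl library. The reverse held for 8395 lost regions, a gain to loss ratio of 2.78 (95% interval 2.68 to 2.87 from a bootstrap of 10 Mb genome blocks). Within single donors the ratio was 1.68 in donor 1 (97076 gained, 57897 lost) and 1.49 in donor 2 (94628 and 63304). The other ways of dividing the 4 libraries 2 against 2 gave 13775 and 12295 regions when conditions were crossed between donors, and 9800 and 18034 regions specific to donor 1 and donor 2. With 3 such divisions an exact permutation test cannot reach 0.05. Gained and lost regions were short and held few tags. Their median widths were 648 bp and 665 bp against 1581 bp for regions found in all 4 libraries. In at least 1 of the libraries holding them, 88.3% and 89.5% had a tallest peak below the median of that list by the authors' normalized tag count. This count is a total over the peak and so depends on its width. The crossed and donor-specific patterns were alike in width and tag count, with median widths of 647 to 662 bp and 88.4 to 90.2% below the median.

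Among regions that changed in both donors, the number of gained regions was close to that expected from independent donors, partly by construction. Of the 57776 regions whose state differed between conditions in both donors, 54.9% changed in the same direction. Independent donors with the same shares of gains among these regions would give 22855 gained and 7939 lost regions. The gained number, 23311, lay 1.99% above this expectation, and the lost number was 8395. These shares include the observed counts, so the difference between gained and lost numbers is fixed. The small gap for gained regions alone therefore could not test independence. The odds ratio for change in the same direction was 1.16, or 0.21 on the log2 scale (95% interval 0.17 to 0.26 over genome blocks), which measures the spread between regions of these 4 libraries and not between donors. It was 0.15 (0.10 to 0.20) when each siPGR library was paired with the siCtrl library of the other donor. Donor-specific regions then take the place of the crossed ones, so the odds ratio stayed above 0 on the log2 scale with donors mismatched. When each list was shortened to its 200573 tallest peaks, the length of the shortest list, gained regions numbered 14958 and lost regions 10341, and the ratio fell to 1.45 (1.405 to 1.486). At equal lengths the log2 odds ratio was 0.21 (0.16 to 0.26). Among peaks of at least 1.5 times the caller's tag threshold, chosen after the data were seen, it was -0.019 (-0.36 to 0.34), an interval that holds both 0 and the value of all regions.

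**Figure D2:**
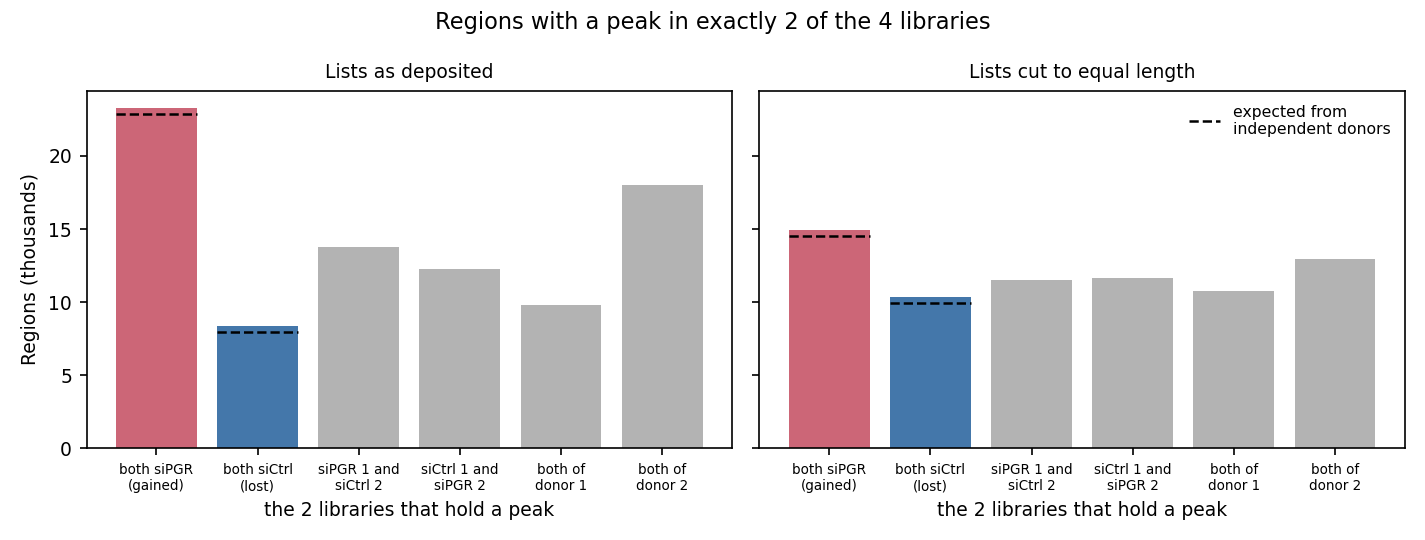
Number of merged regions (in units of 1000) with a peak in exactly 2 of the 4 libraries, by which libraries hold it, for the lists as deposited and shortened to equal length; dashed lines mark the gained and lost numbers expected from independent donors. The gained bar holds 23311 regions against 22855 expected, and 14958 against 14531 at equal length. The expectation takes its shares of gains from the regions changed in both donors, so it includes the observed counts.

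The 10 gained regions that ranked highest within both siPGR lists included sequence at chromosome 3 (196625453 to 196626080), with 1630 ± 83.1 normalized tags (SD, n = 2), and at chromosome 1 (91852539 to 91853464), with 1450 ± 32.0. They also included chromosome 16 (46392778 to 46393665), with 396 ± 16.2, and 2 regions of chromosome 21 (11128339 to 11129498 and 11143730 to 11144497), with 60.0 ± 6.2 and 70.6 ± 24.0 normalized tags. Input tags, scaled to the capture library, were also high at the first of these. They were 862.1 and 1419.2 in donors 1 and 2 at the chromosome 3 region, and 797.1 and 1158.6 at the chromosome 1 region. They were 217.6 and 353.8 at the chromosome 16 region from 46392778, and 20.1 to 59.9 at the remaining regions of the set. In all 10 regions of the set the lower fold over input was below 5, from 4.03 to 4.65, close to the 4-fold minimum of the peak caller. Over all gained regions the lower fold was below 5 in 49.7%, against 51.8% of lost regions and 67.3% of regions found in all 4 libraries. The other sites of the set were chromosome 16 (56376601 to 56380644, 66.9 ± 3.0 normalized tags), chromosome 7 (138517495 to 138520523, 54.2 ± 5.2), chromosome 2 (236943035 to 236945643, 44.8 ± 2.3), and chromosome 17 (37541982 to 37545534 and 4413653 to 4416926, 46.9 ± 3.5 and 44.4 ± 2.4). In 5 of the 10, a siCtrl peak lay within 1 kb of the region.

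The 10 highest-ranking lost regions began with chromosome 2 (133021176 to 133023759), at 132 ± 8.9 normalized tags in siCtrl (SD, n = 2) and no peak in siPGR, and chromosome 16 (46426278 to 46426804), at 74.6 ± 7.9. Others were chromosome 8 (47171607 to 47174501, 38.7 ± 6.5 normalized tags), chromosome 22 (50106604 to 50109026, 36.8 ± 8.6), chromosome 15 (41447973 to 41451015, 35.8 ± 7.7) and chromosome 9 (132283864 to 132287509, 30.4 ± 1.9). The set closed with chromosome 17 (35750214 to 35753249 and 4052740 to 4055713, 34.0 ± 9.5 and 34.2 ± 8.8), chromosome 21 (42514289 to 42515957, 27.8 ± 0.71) and chromosome 3 (192621975 to 192623645, 28.2 ± 1.1). The lower fold over input was below 5 in 8 of the 10. A region without a listed peak can still hold tags below the caller's thresholds, so neither set gives a fold change between conditions.

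Among regions at least 8-fold over input in both libraries that hold them, a filter chosen after the data were seen, 1656 were gained and 471 lost. The highest-ranking gained ones lay on chromosome 9 (86562207 to 86565413, 35.4 ± 4.4 normalized tags), chromosome 2 (203271850 to 203273004, 24.3 ± 1.1), chromosome 8 (136637951 to 136639087, 22.3 ± 2.0), chromosome 13 (100363039 to 100364750, 20.45 ± 4.0) and chromosome 1 (1571685 to 1573045, 20.4 ± 2.7). The highest-ranking lost ones lay on chromosome 17 (75099671 to 75101415, 19.4 ± 4.2), chromosome 2 (242935336 to 242937007, 20.9 ± 7.5), chromosome 19 (9879948 to 9881816, 20.45 ± 8.7), chromosome 10 (81966261 to 81967085, 14.4 ± 0.99) and chromosome 16 (84735706 to 84736747, 15.9 ± 4.9), all as mean ± SD of 2 libraries. Among these 10, a peak of the other condition lay within 1 kb of 3 gained and 2 lost regions. The log2 odds ratio for change in the same direction was 0.49 (0.29 to 0.70) in this subset.

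The third comparison asked where along the genome the changes lay. Regions in parts of the genome with few peaks were gained more often relative to losses than regions in peak-rich parts. Windows of 1 Mb with at most 103 regions held 6091 gained and 1511 lost regions, a ratio of 4.03 (3.78 to 4.29), whereas windows with 257 to 330 regions held 3880 and 1644, a ratio of 2.36 (2.21 to 2.51). The ratio of the 2 crossed patterns was 1.16 and 1.08 in the same groups. Peak-poor windows took 15.6% of the siCtrl and 18.1% of the siPGR regions in donor 1, and 17.5% and 19.4% in donor 2, a mean difference of 2.17 percentage points (exact permutation p = 0.333, the smallest possible for 2 against 2). At equal list lengths the mean difference was 0.932 percentage points. Regions found in all 4 libraries were more common where peaks were dense, at 13.2% of regions in the peak-poor group and 31.3% in the peak-rich group.

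**Figure D3:**
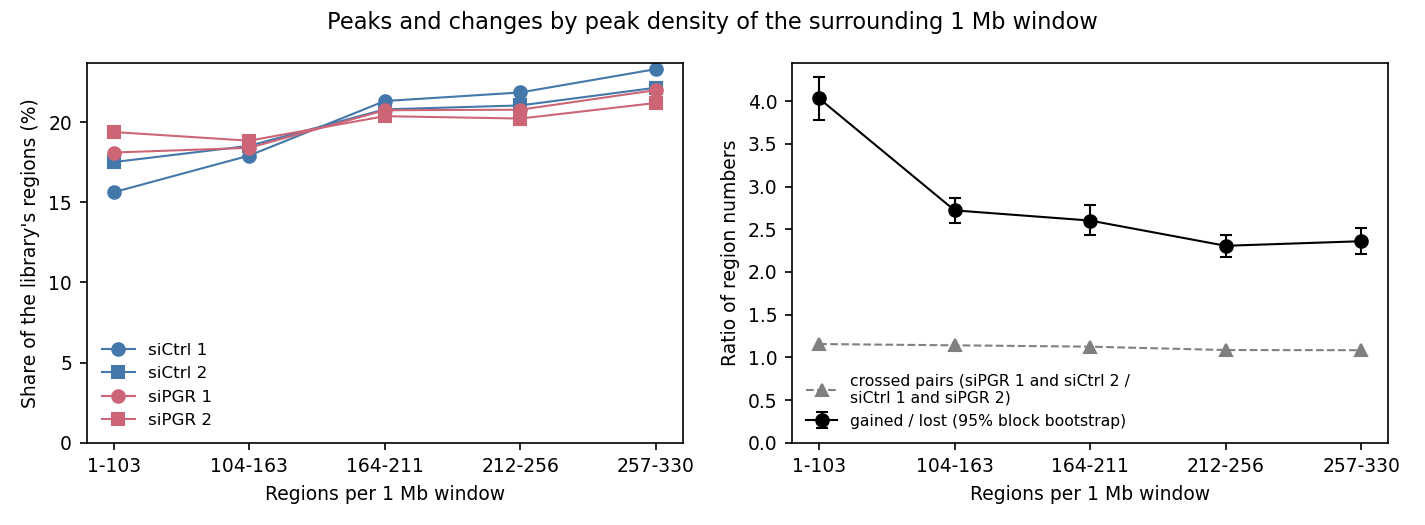
Left, share of each library's regions (%) in 5 groups of 1 Mb windows ordered by regions per window; right, gained over lost regions with 95% block bootstrap intervals, and the ratio of the crossed patterns, by the same groups. The gain to loss ratio is 4.03 in the peak-poor group and 2.36 in the peak-rich group, and both siPGR libraries lie above both siCtrl libraries in the peak-poor group.

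Gains outnumbered losses on each of the 22 autosomes. The ratio was lowest on chromosome 22 (2.22, block bootstrap interval 2.05 to 2.96) and chromosome 16 (2.24, 1.99 to 2.61) and highest on chromosome 4 (3.15, 2.78 to 3.67). A binomial test against the genome-wide share, adjusted by Benjamini-Hochberg over the 22 chromosomes, placed only chromosome 16 apart (adjusted p = 0.0328), and it treats regions as independent. Chromosome 19 had the highest share of regions found in all 4 libraries, at 37.7%, and chromosome 3 the lowest, at 18.6%. Among 2340 windows of 1 Mb with at least 50 regions, 102 had an unadjusted binomial p below 0.05 for gains against losses and 0 passed after Benjamini-Hochberg adjustment (smallest adjusted p = 0.451). The crossed division gave 69 such windows and the donor division 82, with 0 after adjustment in each. The window with the largest excess of gains was chromosome 16 from 68000001 to 69000000, with 26 gained and 3 lost regions. Next, with equal excess, were chromosome 1 from 226000001 to 227000000, with 25 and 3, and chromosome 12 from 32000001 to 33000000, with 27 and 5. Their unadjusted binomial p-values were 0.0568, 0.0556 and 0.168 in this order, none below 0.05. Losses exceeded gains most on chromosome 1 from 26000001 to 27000000, with 13 lost and 6 gained regions.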

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

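Settings at 1.5 and 2 times the tag threshold, at the common floor, by density and for regions at 8-fold over input, and all those for the gain to loss ratio and peak-poor windows, were chosen after the data were seen. The mean peak number was higher in siPGR under each alternative run, but at 8-fold over input it was lower in donor 2 (0.839). With the donors as a replicate block the peak number ratio was 1.15, as without it, and it changed no call. The ratio was 1.03 at 8-fold over input, 1.22 for covered bases, 1.24 with a floor of 10 normalized tags and 2.98 for peaks of at least 2 times the tag threshold; the cause was not tested. Gained and lost regions numbered 14958 and 10341 at equal list lengths, 11209 and 3780 in the upper 50% of each list, 17505 and 5565 with no peak of the other condition within 1 kb, 40255 and 14419 as 1 kb bins, and 33015 and 16389 at a reciprocal overlap of 50%. They numbered 13609 and 2992 with the common floor, 1656 and 471 at 8-fold over input, 1297 and 99 at 1.5 times the tag threshold and 73 and 4 at 2 times. A single donor gave 94628 to 97076 gained and 57897 to 63304 lost regions, since agreement of donors was then not required. The gain to loss ratio over both donors was 1.45 at equal lengths and up to 18.3 at 2 times the tag threshold (8.33 to 79.0). With 1 donor it was 1.49 to 1.68 as deposited, and 1.06 and 1.08 at equal lengths. The log2 odds ratio of donor agreement was -0.019 (-0.36 to 0.34) at 1.5 times the tag threshold, against 0.21 for all regions, and 0.94 (-1.09 to 2.86) at 2 times, where few regions were left; the cause was not tested. In the other settings it was 0.15 to 0.49, each with an interval above 0, and lowest with the donors swapped between pairs. The excess of siPGR regions in peak-poor windows fell from 2.17 to 0.932 percentage points at equal lengths and 1.52 in the upper 50%. Promoter, gene list, reference list and GC alternatives were not run for want of an hg19 annotation and sequence, and the agreement of donors has no value with 1 donor left out. Depth limits what absence of a peak means: at the caller's threshold a region with fewer than 15 tags in 500 bp (20 in 1 library) is not listed.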

Other observations

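Equal list lengths and the odds ratio without the replicate block were fixed before the data were examined. The latter paired each siPGR library with the siCtrl library of the other donor. The tests on depth, the input filter, peak density, peak-poor windows and the header, and the use of equal lengths to weigh an explanation, were chosen after the results were seen.

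The tallest peaks by normalized tags lay in few places. On the autosomes, 20 regions reached at least 1000 normalized tags, in 3 of the 4 libraries, and 1 library held no peak of this height. The tallest were chromosome 10 from 42596778 to 42601590, with up to 13591 normalized tags and a peak in 4 libraries, chromosome 10 from 42383775 to 42389270, with up to 10518 and a peak in 3, and chromosome 21 from 9825422 to 9828112, with up to 9001 and a peak in 3. The 41 peaks of this height were 4.08 to 8.84-fold over input, against list medians of 5.61 to 5.92. Input tags were thus high there too, so the height alone does not measure capture. Of these regions, 30% were absent from at least 1 list.

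More regions were gained than lost in both donors. Sequencing depth does not account for this in donor 1, since siPGR had 0.975 times the tags of siCtrl there and still more peaks. In donor 2 siPGR had 1.54 times the tags of siCtrl, so a part of depth in that donor stays open. The input filter does not account for the excess of gains, as it removed at most 220 more candidates from siCtrl than from siPGR of the same donor, where siPGR had 36359 more peaks. At equal list lengths the gain to loss ratio was 1.45 (1.405 to 1.486) over both donors, and 1.06 and 1.08 within donors. Independent donors would give 1.47, taking the shares of gains among regions changed in both donors rather than the within-donor ratios. Those shares include the observed counts, so the nearness of 1.45 to 1.47 could not test independence. At these lengths the siPGR excess in peak-poor windows was 0.932 percentage points (1.204 and 0.659 in the donors) against 2.17 as deposited. Equal lengths bring gains and losses within a donor close together by construction, so longer lists from stronger capture and a wider methylated genome after PGR siRNA cannot be told apart without a spike-in.

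Regions changed in the same direction in both donors slightly more often than independent donors would give. Unequal peak density between 5 groups of 1 Mb windows does not explain it, as the log2 odds ratio stratified by these groups was 0.19 (0.15 to 0.24). Density on a finer scale was not tested. The log2 odds ratio was 0.21 (0.16 to 0.26) at equal list lengths. This measure does not move with list length alone, so that value could not test unequal list lengths. A response to PGR siRNA remains open. So do stronger capture and deeper input, which both siPGR libraries share, and base composition of the fragments, none of which was tested against this measure. Among peaks of at least 1.5 times the tag threshold no excess was detected, at -0.019 (-0.36 to 0.34), an interval that holds the 0.21 of all regions, while it was 0.26 in the upper 50% of each list, 0.26 with the common floor and 0.49 at 8-fold over input. With each siPGR library paired to the siCtrl library of the other donor, the value was 0.15. Simulated lists with no effect gave 0.02, but there each library held every region with the same probability. That value is therefore no background for the real lists.

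As a hypothesis, the list labelled siCtrl whose header names a PGR siRNA could be a PGR siRNA library. The remaining siCtrl list would then be the odd one out. At equal list lengths, 17572 regions lacked a peak only in that remaining list, 21695 only in the list in question, and 12467 and 13466 only in a siPGR list. The order is the opposite of the prediction, but weak capture in 1 library gives the same order with either label, so the question stays open.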
